A study of Mus musculus with 15 samples.

How the data were processed

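Mouse embryonic fibroblasts expressing EZHIP from a lentivirus were profiled by chromatin immunoprecipitation with antibodies to EZH2, FLAG and H3K27me3. Per the labels' protocols, cells were fixed with paraformaldehyde, chromatin was digested to mono-nucleosomes with micrococcal nuclease and immunoprecipitated overnight, and libraries followed the NEB Next Ultra protocol. The EED-null line was derived from floxed cells with Cre recombinase as a single clone, per the labels' protocols. Groups were taken from the sample titles, giving 15 groups of 1 library each. Peak lists of 3 libraries were used, from EED-floxed cells with wild-type EZHIP, and the other 12 libraries were not used here.

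Per the submitters' processing notes, Bowtie 1.0.0 and deepTools were used and the genome build was mm9. The peak caller, its thresholds, any control library and the read depth are not given in the sources used here. The authors' deposited lists hold the start and end position of each peak, in bp, with no score, height, fold enrichment or p-value, and there is 1 list per library, so nothing was pooled. In the deposited lists, which count starts from 0, all starts are multiples of 200 bp and all ends lie 1 bp below such a multiple. Printed starts are counted from 1 and so lie 1 bp higher. The narrowest interval was 399 bp, and widths differ in steps of 200 bp. Because the lists carry positions only, a stricter calling threshold could not be applied. Peaks up to the lower quartile of width in each list were left out instead, and whether these are the weaker peaks is unknown without scores. Mono-nucleosome chromatin and a 200 bp grid limit the resolution of edges to about that step.

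Overlap was counted where peaks shared at least 1 bp, with exact Clopper-Pearson 95% intervals. Chance was estimated from 1000 random placements per list, keeping each peak's width and chromosome, without overlap within the list, between the first start and the last end seen on that chromosome in the 3 lists. Unmappable sequence was not excluded from the placements. The p-value of these one-sided permutation tests was the share of placements with at least the observed overlap, 1 added to both counts. Widths were compared by a two-sided permutation test of the difference in median log2 width with 100000 resamples. Peaks of 2 lists that overlapped each other and nothing else in those lists were paired, and the log2 width ratio was tested by flipping signs at random 100000 times. Sites with both signals were chains of overlapping peaks, compared by the bp covered. The pairing, the sites, the test of each chromosome, the division by quartile or class of width and the stretches of chromosomes 5 and 7 were added after the data were examined, whereas the split of EZH2 peaks at the median width was fixed beforehand for the overlap with H3K27me3. Shares were compared with two-sided Fisher's exact tests. Clusters joined peaks with gaps of at most 100 kb and were tested against the same placements. The distribution over chromosomes was tested by 100000 permutations of list membership. Benjamini-Hochberg adjustment was made within the main families of tests for overlap, width, paired width, clusters and chromosomes. Other p-values were not adjusted, among them the Fisher's exact tests of H3K27me3 and FLAG shares, the alternatives and the tests of explanations.

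Regions are named by a rule set before the data were examined. Peaks of the 3 lists that overlapped or lay within 5 kb were joined, and the 10 regions with peaks of all 3 lists and the most peaks were named, ties going to the longer covered length. The 3 widest peaks of each list, the 3 clusters of each list with the most peaks, and the 3 widest peaks of each list with no other signal within 5 kb were also named. Gene names, promoter overlap, the overlap with 8 gene lists fixed beforehand (Hox clusters, other homeobox and Pax factors, further developmental transcription factors, signalling genes, cell cycle inhibitors and imprinted genes, Polycomb subunits, housekeeping genes and fibroblast genes) and base composition were left out. They need annotation or sequence of build mm9, which was not used here, and coordinates were not converted between builds.

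The procedures were tested on simulated data. FLAG-like lists placed at random gave p of at most 0.05 in 4% of 100 lists for overlap and 5% for clustering. These lists came from the same random placement as the chance estimate and lacked the clustering of the real lists. The rates therefore check the computation and not its error rate on clustered lists. Lists with 10.0% of their peaks set on EZH2 peaks returned 9.95% above chance, and 100% of 20 such lists passed. Shuffled EZH2 widths passed the width test in 2.5% of 40 shuffles, and a doubling (log2 of 1) of 400 widths was recovered as 0.96. Alternatives fixed beforehand were a required overlap of 50% of the smaller peak, distances of 1 and 5 kb, rotation of whole chromosomes, moves of 20 to 100 kb, joining within 5 kb, 1 peak per cluster, cluster gaps of 50 and 200 kb, a midpoint within 500 bp, and the omission of narrow peaks, of chromosomes X and Y, or of each chromosome in turn. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.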

Results

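Chromatin immunoprecipitation with sequencing was used to map EZH2, the catalytic subunit of the H3K27 methyltransferase complex PRC2, together with the FLAG epitope and H3K27me3, in mouse embryonic fibroblasts that stably express EZHIP. EZHIP is a protein inhibitor of PRC2, and the FLAG signal was read as tagged EZHIP because the series design names EZHIP as the third profiled target. The series holds 15 libraries, from 5 cell conditions and 3 antibodies, with 1 library per combination. The conditions are DMSO, tazemetostat (an inhibitor of EZH2 catalysis), EED-floxed cells with wild-type EZHIP, EED-null cells with wild-type EZHIP, and EED-floxed cells with the EZHIP variant M406E. EED is the PRC2 subunit that binds H3K27me3 and stimulates the enzyme. Peak lists of 3 libraries were analysed, all from EED-floxed cells with wild-type EZHIP. The other 12 libraries were not analysed here, so no effect of tazemetostat, of EED loss or of M406E was measured. Each list gives positions only, so read depth, peak height and enrichment are unknown. There were no replicates, and every test below compares these 3 lists and not conditions. Tests over peaks treat neighbouring peaks as independent, and the intervals cover counting error only. Coordinates are in mouse build mm9, counted from 1, and gene annotation of that build was not used here.

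The H3K27me3 list held the most peaks, over the widest range of widths. The H3K27me3 list held 1126 peaks covering 9.26 Mb, with a median width of 4599 bp (interquartile range 1999 to 8949 bp). The EZH2 list held 902 peaks covering 6.22 Mb, with a median of 5199 bp (3399 to 8149 bp). FLAG gave 438 peaks over 2.21 Mb, with a median of 3999 bp (2399 to 5999 bp). H3K27me3 peaks ranged from 399 to 165999 bp, and the 102 peaks wider than 20 kb held 41.8% of all H3K27me3 bases. EZH2 had 40 peaks of that width and FLAG had 5. In two-sided permutation tests of the median log2 width, EZH2 peaks were wider than FLAG peaks by 0.38 (p = 1e-05, the smallest that 100000 permutations can give; adjusted p = 3e-05 over 3 tests). H3K27me3 peaks were narrower than EZH2 peaks by a median log2 difference of -0.18 (permutation p = 0.00902, adjusted p = 0.0135) and wider than FLAG peaks by 0.20 (permutation p = 0.0359, adjusted p = 0.0359), a call that was lost when peaks within 5 kb were joined (permutation p = 0.0638). These differences depend on the narrowest peak in each list, which was 2199 bp for EZH2, 1199 bp for FLAG and 399 bp for H3K27me3. Peaks of at least 2199 bp numbered 840 for H3K27me3, 902 for EZH2 and 349 for FLAG, so H3K27me3 no longer had the most. Among these peaks, H3K27me3 became wider than EZH2 by 0.25 and exceeded FLAG by 0.37 (permutation p = 1e-05 for both, the smallest possible), and EZH2 exceeded FLAG by 0.12 with a permutation p of 0.161.

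FLAG-tagged EZHIP lay almost entirely at sites of PRC2. Of 438 FLAG peaks, 423 overlapped an EZH2 peak, or 96.6% (exact Clopper-Pearson 95% interval 94.4 to 98.1%). H3K27me3 was present at 432 FLAG peaks, or 98.6% (97.0 to 99.5%). By bases, 98.0% of FLAG coverage fell within EZH2 peaks and 99.4% within H3K27me3 peaks. The reverse did not hold, since 410 of 902 EZH2 peaks, or 45.5% (42.2 to 48.8%), overlapped a FLAG peak. Random placement of the same peaks within their chromosomes gave a mean share of 0.521% for FLAG over EZH2, 0.763% for FLAG over H3K27me3 and 0.254% for EZH2 over FLAG. All 6 ordered overlaps between the lists exceeded every placement (permutation p = 0.000999, one-sided, the smallest that 1000 placements can give, unchanged by Benjamini-Hochberg adjustment over 6 tests).

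**Figure D1:**
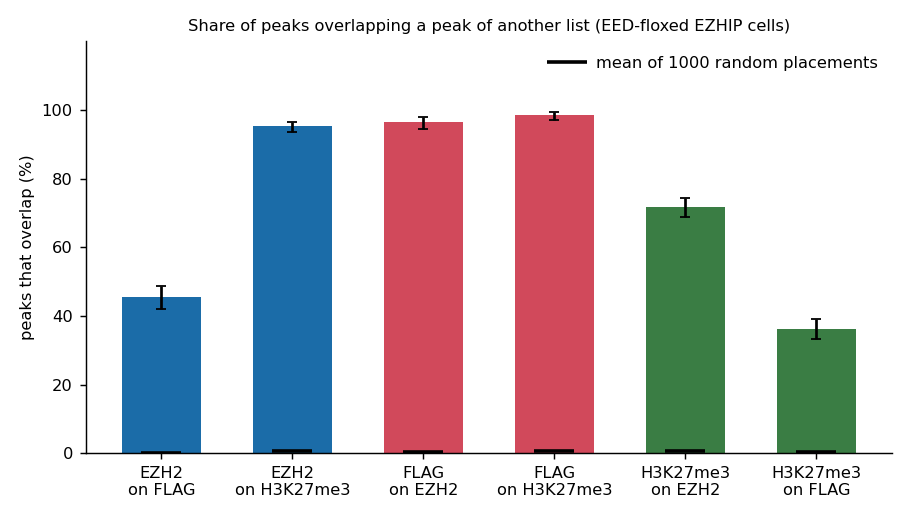
Percentage of peaks of each list that overlap a peak of another list by at least 1 bp, on a vertical axis in percent, with exact 95% intervals as error bars and the mean of 1000 random placements as black dashes. FLAG peaks sit at 96.6% on EZH2 and 98.6% on H3K27me3, whereas EZH2 peaks sit at 45.5% on FLAG and the placements stay near 0%.

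Nearly all EZH2 peaks overlapped H3K27me3, and most H3K27me3 peaks carried EZH2. H3K27me3 overlapped 859 of 902 EZH2 peaks, or 95.2% (93.6 to 96.5%), against a mean of 0.834% for random placements. EZH2 overlapped 807 of 1126 H3K27me3 peaks, or 71.7% (68.9 to 74.3%), against 0.656%. FLAG overlapped 407 of 1126 H3K27me3 peaks, or 36.1% (33.3 to 39.0%), against 0.305%. By bases, 86.5% of EZH2 coverage lay within H3K27me3 peaks, and 58.1% of H3K27me3 coverage lay within EZH2 peaks. Merging overlapping peaks of the 3 lists gave 1175 regions, of which 401 held all 3 signals, 34.6% held EZH2 and H3K27me3 without FLAG, and 313 held H3K27me3 alone. EZH2 alone formed 43 regions, FLAG alone formed 6, and FLAG with H3K27me3 formed 6. No peak pair of EZH2 and FLAG lacked H3K27me3. H3K27me3 was found at all 410 EZH2 peaks with FLAG (100%, 99.1 to 100%) and at 449 of 492 without FLAG (91.3%, 88.4 to 93.6%; two-sided Fisher's exact p = 2.89e-12). Among the 440 EZH2 peaks wider than the median these shares were 100% and 97.5% (Fisher's exact p = 0.0327). Among the other 462 they were 100% and 90.0% (Fisher's exact p = 0.0146). With EZH2 peaks divided at the quartiles of width, H3K27me3 was present at 225 of 226 in the widest group. In the next widest group it was present at 224 of 225, so the difference among wider peaks rests on very few peaks. FLAG was present at 0 of 226 in the narrowest group, so the narrower peaks were not matched for width. Conversely, FLAG was found at 401 of 807 H3K27me3 peaks with EZH2, or 49.7%, and at 6 of 319 without EZH2, or 1.88% (Fisher's exact p = 3.16e-65). This largely restates the overlap of FLAG with EZH2 and does not account for width. Of the 319, 173 were under 2199 bp, and no H3K27me3 peak with FLAG was narrower than 2399 bp. Of the 6, 4 lay past the last EZH2 peak of chromosome 7.

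The series title concerns the spreading of H3K27 methylation, and the extent of H3K27me3 around each EZH2 peak is a measure that bears on part of it. At sites where a single H3K27me3 peak met a single EZH2 peak, the methylated interval was slightly shorter than the EZH2 interval. Across 764 such pairs the median width was 4799 bp for H3K27me3 and 5199 bp for EZH2, with a median ratio of 0.900 (interquartile range 0.750 to 1.00). H3K27me3 was narrower in 553 pairs, wider in 159 and equal in 52 (median log2 ratio -0.15; sign-flip permutation p = 1e-05, the smallest possible). The narrowest peak was 2199 bp for EZH2 and 399 bp for H3K27me3, so every paired H3K27me3 peak under 2199 bp had to count as narrower. Neither pairs nor sites were tested with a common narrowest width. In the widest quartile group of paired EZH2 peaks, with a median of 11399 bp, the median edge distance was still -400 bp (191 pairs). The median H3K27me3 edge lay 400 bp inside the EZH2 edge, a signed distance of -400 bp (interquartile range -600 to 0 bp), and 87.4% of 1528 edges lay within 1 kb of each other. H3K27me3 reached more than 5 kb beyond the EZH2 edge at 20 edges of these pairs, or 1.31%. The pairs leave out 43 sites where a single H3K27me3 peak spanned several EZH2 peaks, 95 in all, and there H3K27me3 covered 1.27 Mb against 0.832 Mb of EZH2. Over all 807 sites with both signals, H3K27me3 covered 6.32 Mb and EZH2 6.09 Mb, although the median site still had less H3K27me3 than EZH2 (ratio 0.909; less at 554 sites, more at 201; sign-flip permutation p = 1e-05, the smallest possible). At 25 of 1614 outer edges of these sites, or 1.55%, H3K27me3 reached more than 5 kb beyond EZH2. These extents follow the authors' peak calls, whose thresholds and joining of neighbouring peaks are not given in the sources used here. H3K27me3 peaks without any EZH2 peak enter neither the pairs nor the sites. Among them, the 313 with neither EZH2 nor FLAG held 30.2% of all H3K27me3 bases. Chromosome 5 weighed heavily in this share, since 22 of these peaks, all wider than 20 kb and on that chromosome, held 12.8% of all H3K27me3 bases. The extents therefore describe methylation at EZH2 peaks only. Whether methylation spread less or more than in cells without EZHIP was not measured.

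FLAG intervals were nested within EZH2 intervals. In all 399 pairs of a single EZH2 and a single FLAG peak, the FLAG peak lay inside the EZH2 peak, with a median EZH2 to FLAG width ratio of 1.92 (1.54 to 2.70; log2 0.94; sign-flip permutation p = 1e-05, the smallest possible). EZH2 reached a median of 1800 bp beyond FLAG on each side (1400 to 2400 bp). H3K27me3 was likewise wider than FLAG in all 387 of their pairs, with a median ratio of 1.83.

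**Figure D2:**
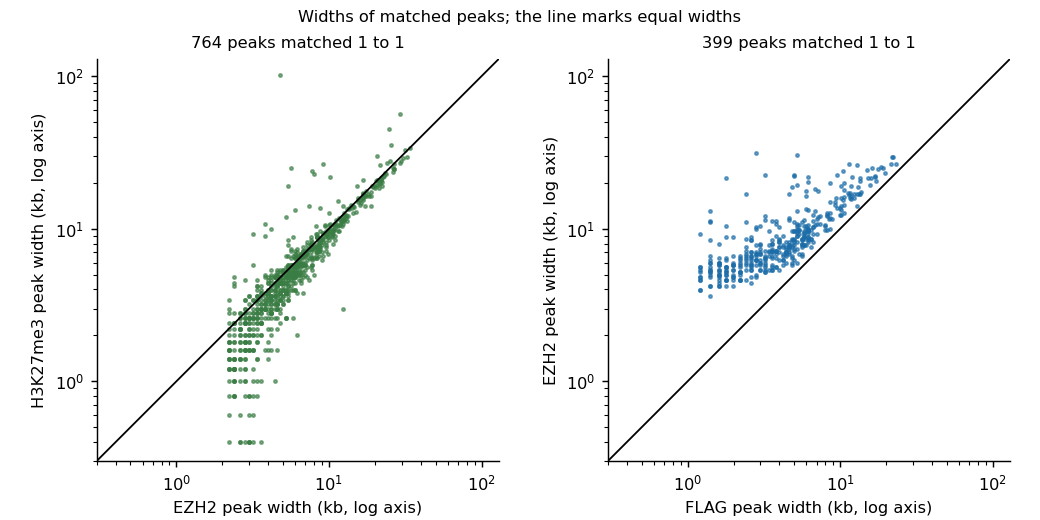
Widths of peaks matched 1 to 1, in kb on log axes, for H3K27me3 against EZH2 (764 pairs, left) and EZH2 against FLAG (399 pairs, right), with a line of equal width. The left points lie around and slightly below the line, with a median ratio of 0.900, and all points on the right lie above it, with a median ratio of 1.92.

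FLAG peaks were called mostly at wide EZH2 peaks and not at the narrowest ones. EZH2 peaks with FLAG had a median width of 7799 bp, against 3599 bp for those without (log2 difference 1.12; permutation p = 1e-05, the smallest possible; 410 and 492 peaks). With EZH2 peaks divided by width at the quartiles, FLAG was present, from the narrowest to the widest group, at 0 of 226 (exact upper bound 1.62%), 44 of 225 (19.6%), 169 of 225 (75.1%) and 197 of 226 (87.2%). H3K27me3 was present at 85.0%, 96.9%, 99.6% and 99.6% of the same groups. The narrowest EZH2 peak with FLAG spanned 3599 bp, and the 235 narrower peaks had none. In the paired peaks EZH2 reached 1400 to 2400 bp beyond FLAG on each side (interquartile range), and no FLAG peak was narrower than 1199 bp. The narrowest EZH2 peaks thus had little room for a FLAG call, so their lack of FLAG does not show a lack of EZHIP. Among the 370 EZH2 peaks of at least 5999 bp, the FLAG share was 82.6% for those up to their median of 8999 bp and 87.8% for the wider ones (Fisher's exact p = 0.189), so a dependence on width was detected only when smaller peaks were included. H3K27me3 peaks with EZH2 showed the same contrast, with a median width of 7799 bp for the 401 with FLAG and 2999 bp for those without (log2 difference 1.38; permutation p = 1e-05, the smallest possible).

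**Figure D3:**
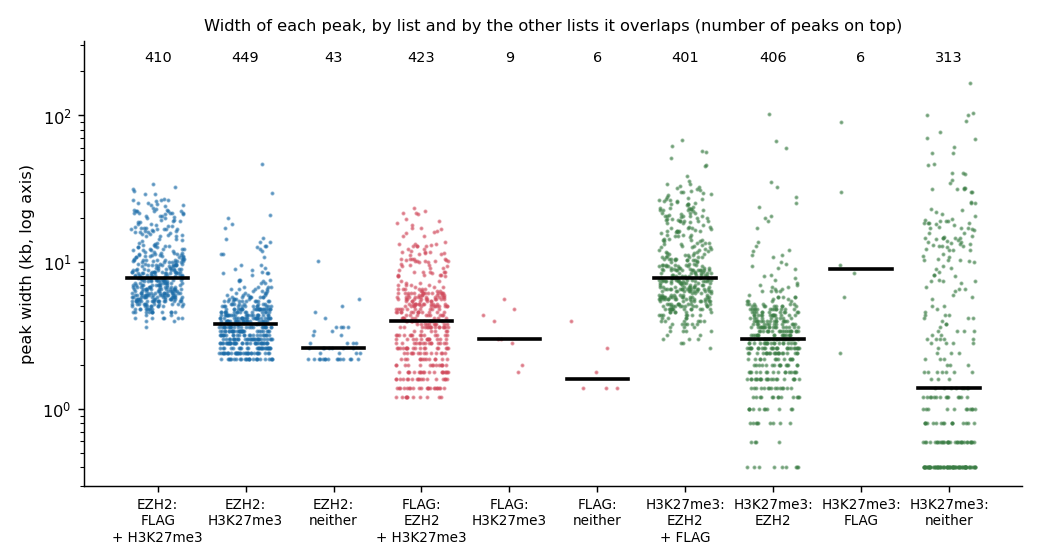
Width of every peak in kb, on a log axis, grouped by list and by the other lists it overlaps, with black bars for medians and the number of peaks above each group. EZH2 peaks with FLAG and H3K27me3 have a median of 7799 bp and those with neither 2599 bp, and H3K27me3 peaks with neither mark range from 399 to 165999 bp around a median of 1399 bp.

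Regions holding all 3 signals included long intervals with several EZH2 and FLAG peaks under a single H3K27me3 peak. The region with the most peaks was chromosome 7 from 86639201 to 86703599, where 3 EZH2 peaks and 3 FLAG peaks lay under 1 H3K27me3 peak covering 62399 bp. On chromosome 2, the region from 19346601 to 19378799 held 2 EZH2 and 3 FLAG peaks, and the region from 74485601 to 74537599 held 3 EZH2 peaks and 1 FLAG peak of 4999 bp under 51599 bp of H3K27me3. Chromosome 4 from 139372801 to 139412399 held 2 EZH2 and 2 FLAG peaks, with 19598 bp of FLAG. Chromosome 19 from 6398801 to 6432799 held 3 EZH2 peaks and 1 FLAG peak. A single EZH2 peak with 3 FLAG peaks inside spanned the region on chromosome 3 from 34537601 to 34570199 and that on chromosome 14 from 49270401 to 49297199. Chromosome 9 from 37238401 to 37270399, chromosome 11 from 103608201 to 103638999 and chromosome 7 from 25713601 to 25741799 each held 2 EZH2 and 2 FLAG peaks. All 10 regions had a single H3K27me3 peak. The narrowest gap between neighbouring peaks was 1201 bp in the EZH2 list, 2201 bp in the FLAG list and 2801 bp in the H3K27me3 list. Gaps under 5 kb numbered 28, 10 and 1. The number of peaks per region may thus also reflect how each list joined neighbouring peaks, which was not tested.

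The widest single peaks differed between the lists. For EZH2 this was chromosome 9 from 91245601 to 91291999, a 46399 bp peak with H3K27me3 and no FLAG, followed by chromosome 19 from 44806001 to 44839999 (33999 bp) and the chromosome 3 region above, both with FLAG and H3K27me3. The widest FLAG peaks were chromosome 5 from 140011201 to 140034599 (23399 bp), chromosome 8 from 12382201 to 12404399 (22199 bp) and chromosome 5 from 35723601 to 35745399 (21799 bp), all with both other signals. The widest H3K27me3 peaks were chromosome 5 from 129688601 to 129854599 (165999 bp) and chromosome 5 from 146473801 to 146576999 (103199 bp), neither of which had EZH2 or FLAG. The peak at chromosome 15 from 84211601 to 84313799 (102199 bp) had EZH2 and no FLAG.

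Peaks with a single signal were mostly narrow. The 43 EZH2 peaks with neither other signal had a median width of 2599 bp, and the widest were chromosome 10 from 21869401 to 21879599, chromosome 13 from 3355801 to 3361399 and chromosome 10 from 102489401 to 102494399. Lone FLAG peaks numbered 6, the widest being chromosome 8 from 19708601 to 19712599, chromosome 11 from 88829401 to 88831999 and chromosome 5 from 15143001 to 15144799. The 313 H3K27me3 peaks with neither EZH2 nor FLAG had a median of 1399 bp, and 138 of them were under 1000 bp. The same group also held 33 peaks wider than 20 kb and 30.2% of all H3K27me3 bases. Of these wide peaks, 22 lay on chromosome 5 and held 12.8% of all H3K27me3 bases, among them chromosome 5 from 129247201 to 129348199 (100999 bp).

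H3K27me3 without EZH2 was most frequent among peaks under 1 kb and, on chromosome 5, was also frequent among peaks above 5 kb. EZH2 was present at 33 of 171 H3K27me3 peaks under 1 kb (19.3%, 13.7 to 26.0%), 384 of 456 between 1 and 5 kb (84.2%, 80.5 to 87.4%), 323 of 397 between 5 and 20 kb (81.4%, 77.2 to 85.1%) and 67 of 102 above 20 kb (65.7%, 55.6 to 74.8%). The lower share of the widest class rested on chromosome 5, where 8 of 30 such peaks had EZH2 (26.7%, 12.3 to 45.9%), as did 34 of 64 between 5 and 20 kb (53.1%, 40.2 to 65.7%). On the other chromosomes 59 of 72 did (81.9%, 71.1 to 90.0%), beside 289 of 333 between 5 and 20 kb (86.8%, 82.7 to 90.2%). H3K27me3 peaks with EZH2 had a median width of 4999 bp and those without 1399 bp (log2 difference 1.84; permutation p = 1e-05, the smallest possible; 807 and 319 peaks). When EZH2 was instead required within 500 bp of the H3K27me3 midpoint, a criterion that does not favour wide peaks, the medians were 4799 and 2399 bp (log2 difference 1.00; permutation p = 1e-05, the smallest possible). The direction turned when peaks under 2199 bp, the narrowest EZH2 width, were left out. The medians were then 5599 bp with EZH2 and 12699 bp without (log2 difference -1.18; permutation p = 1e-05, the smallest possible; 694 and 146 peaks), and 5599 and 10399 bp with chromosome 5 left out as well (log2 difference -0.89; permutation p = 1e-05, the smallest possible).

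Chromosome 5 held a large part of the methylated peaks that lacked EZH2. There, 73 of 143 H3K27me3 peaks had no EZH2 (51.0%, 42.6 to 59.5%), against 25.0% of the 983 peaks elsewhere (Fisher's exact p = 1.10e-09, adjusted p = 2.30e-08 over 21 chromosomes). With 1 peak per 100 kb cluster, the difference fell from 26.0 to 17.2 points, with shares of 40.6% of 101 peaks and 23.4% elsewhere (Fisher's exact p = 0.000379). Of the 35 H3K27me3 peaks wider than 20 kb without EZH2, 22 were on chromosome 5, all between 105105601 and 148848199, and none of these 22 had FLAG. Past 100 Mb, 60 of 95 H3K27me3 peaks on this chromosome lacked EZH2 (63.2%), and below 100 Mb 13 of 48 did (27.1%). Chromosome 2 went the other way, with 12 of 97 peaks lacking EZH2 (12.4%) against 29.8% elsewhere (Fisher's exact, adjusted p = 0.00145). The other chromosomes did not pass the adjusted threshold of 0.05. Chromosome 5 was singled out after its values were seen.

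The EZH2 list ended early on chromosome 7. Its last peak there ended at 144516199, whereas H3K27me3 continued with 14 peaks from 146130601 to 152083599, 4 of them with FLAG. On the other chromosomes with EZH2 peaks, at most 2 H3K27me3 peaks and no FLAG peak lay past the last EZH2 peak. The same stretch held 5 of the 15 FLAG peaks without EZH2. Without this stretch, EZH2 was present at 97.7% of 433 FLAG peaks and at 72.6% of 1112 H3K27me3 peaks. A further 3 FLAG peaks without EZH2 lay in a single 89599 bp H3K27me3 peak at chromosome 8 from 126058801 to 126148399. Both stretches were chosen after their values were seen.

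**Figure D4:**
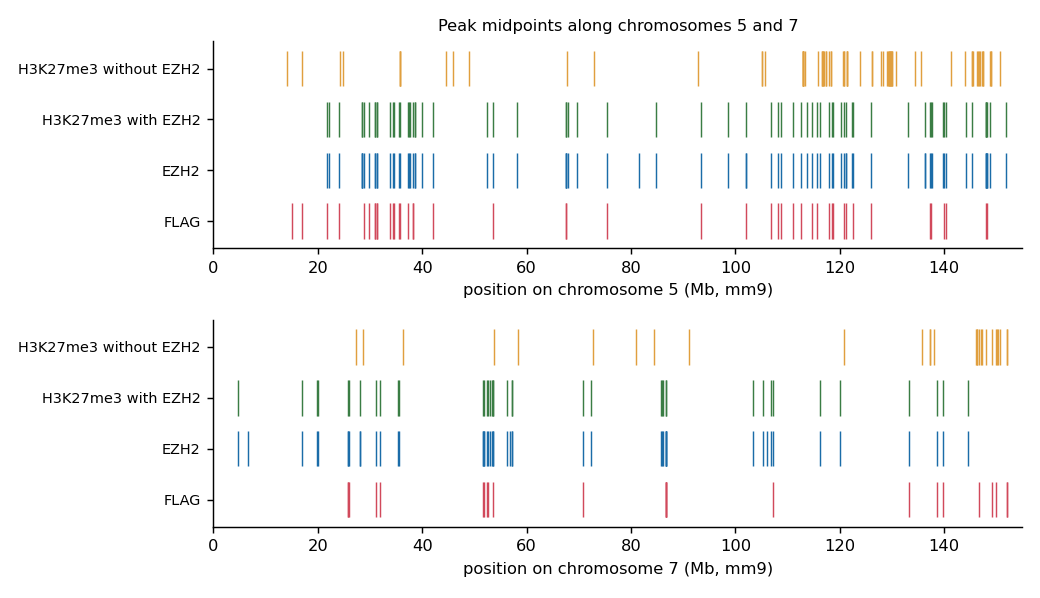
Midpoints of peaks along chromosomes 5 and 7 (horizontal axes in Mb, mm9), with 1 line per peak for FLAG, EZH2, and H3K27me3 with and without an EZH2 peak. On chromosome 5, 60 of the 73 H3K27me3 peaks without EZH2 lie past 100 Mb, and on chromosome 7 the last 14 H3K27me3 peaks lie past the last EZH2 peak.

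All 3 kinds of peak were clustered along the chromosomes. With neighbours joined across gaps of at most 100 kb, EZH2 formed 776 clusters against a mean of 866 for random placements, FLAG 388 against 429 and H3K27me3 974 against 1067 (permutation p = 0.000999 in each, one-sided, the smallest that 1000 placements can give). Shared clusters held 24.3% of EZH2, 20.1% of FLAG and 23.1% of H3K27me3 peaks. The EZH2 cluster with the most peaks was chromosome 15 from 102739601 to 102807399, with 6 EZH2 peaks, 1 H3K27me3 peak and no FLAG, and the next were chromosome 5 from 147992801 to 148214199 and chromosome X from 11575801 to 11737599, with 5 EZH2 and 2 FLAG peaks each. FLAG clustered most at chromosome 19 from 44743601 to 44911199 and chromosome 7 from 86641801 to 86738999, each with 4 FLAG and 4 EZH2 peaks, and at chromosome 19 from 25578401 to 25749399, with 3 of each. H3K27me3 clusters led with chromosome 15 from 73942401 to 74410599, which had 6 H3K27me3 and 2 EZH2 peaks. Next came chromosome 5 from 129607801 to 129977599, with 5 H3K27me3 peaks and neither other signal, and chromosome 15 from 83554001 to 83874199, with 5 H3K27me3 peaks and 1 EZH2 peak. The distribution of peaks over chromosomes was not found to differ between lists in permutation tests of chi-square (16.0 with p = 0.723 for H3K27me3 and EZH2, 20.7 with p = 0.416 for H3K27me3 and FLAG, 13.3 with p = 0.826 for EZH2 and FLAG; adjusted p = 0.826 in each). These tests take all chromosomes together and can miss a difference at a single chromosome. Chromosome 5, picked after its values were seen, held 12.7% of H3K27me3 peaks (10.8 to 14.8%). It held 8.54% of EZH2 peaks (6.80 to 10.6%) and 10.3% of FLAG peaks (7.59 to 13.5%).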

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

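The settings with a common narrowest width, those without chromosome 5 or the end of chromosome 7, and all alternatives for paired widths and for chromosome 5 were chosen after the data were seen. Of 129 alternatives over 24 results, 99 were fixed beforehand and 30 added. Of the 120 with a test, leaving out 3 that merged no peaks, 115 kept the direction, where the test has one, and the side of the 0.05 threshold. The other 6, without a test, left the number of peaks within 1.5 times. All alternatives for the 6 overlaps kept both, with a highest chance share of 3.73% (FLAG over H3K27me3, peaks moved by 20 to 100 kb). These alternatives, 13 per overlap, lay far above chance in every setting, so they had little room to change and raise the tally. Some others left the compared peaks as they were, for instance EZH2 widths with FLAG within 1 kb (410 and 492 peaks). The shares ranged from 96.2 to 97.7% for FLAG over EZH2, 98.5 to 99.4% for FLAG over H3K27me3, 36.8 to 47.7% for EZH2 over FLAG, 82.7 to 96.7% for EZH2 over H3K27me3, 70.2 to 82.6% for H3K27me3 over EZH2 and 35.1 to 39.2% for H3K27me3 over FLAG. The exceptions were all widths. Paired widths were not tested with a common narrowest width. With peaks under 2199 bp left out, which removes narrow H3K27me3 and FLAG peaks and no EZH2 peak, the H3K27me3 width difference with and without EZH2 reversed to -1.18 (-0.89 without chromosome 5), that between H3K27me3 and EZH2 reversed to 0.25, and that between EZH2 and FLAG fell to 0.12 (permutation p = 0.161). After joining within 5 kb, H3K27me3 exceeded FLAG by 0.20 with a permutation p of 0.0638, and the cause was not tested. Joining within 1 kb merged no peaks, as the narrowest gap was 1201 bp, and says nothing of stability. Promoter overlap, gene list overlap and base composition, with their alternatives, were not run. No paired analysis was possible because each group has 1 library. Unknown depth limits any reading of a missing peak as a missing signal.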

Other observations

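The tests of the narrow-peak limit, of the lists without chromosome 5, of the chromosome 5 stretch past 100 Mb, of EZH2 peaks with ample room for FLAG, and of the end of chromosome 7 were chosen only after the pattern was seen.

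EZH2 reached beyond FLAG in all width groups of the paired peaks. From the narrowest to the widest quartile group of FLAG peaks, EZH2 reached a median of 1800, 1800, 1600 and 2100 bp further on each side, while the EZH2 to FLAG width ratio went from 3.11 to 1.42. From the narrowest to the widest quartile group of paired EZH2 peaks, the distances were 1600, 1600, 2000 and 2800 bp. For H3K27me3 against EZH2, the median edge distances from the narrowest to the widest quartile group of EZH2 peaks were -400, -400, -200 and -400 bp. The 10 FLAG peaks without EZH2 outside the end of chromosome 7 included the 3 in the wide H3K27me3 peak of chromosome 8. They also included a pair of 1399 bp peaks on chromosome 4, from 146710001 to 146711399 and from 146794401 to 146795799, neither with H3K27me3.

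Of 1126 H3K27me3 peaks, 319 had no EZH2 peak, and the wide ones gathered on chromosome 5. Narrow peaks that the EZH2 list could not hold were argued against as the whole cause, because 146 of 840 H3K27me3 peaks of at least 2199 bp (17.4%, 14.9 to 20.1%) also lacked EZH2, although the share was 60.5% among the 286 narrower peaks. Chromosome 5 alone was argued against too, since 246 of 983 peaks elsewhere (25.0%, 22.3 to 27.9%) lacked EZH2. Each of these tests kept peaks that the other cause could account for. With peaks under 2199 bp and chromosome 5 both left out, 85 peaks lacked EZH2 and 631 had it, so 11.9% lacked it. For the chromosome 5 stretch past 100 Mb, the density of H3K27me3 peaks without EZH2 was 7.65 times that below 100 Mb and the density of EZH2 peaks 1.70 times (Fisher's exact p = 6.07e-05, too small because the boundary was placed where such peaks gather). Calls need not rise in proportion to copies, which lists without depth cannot show, and EZH2 was denser there too, so extra copies or background may still contribute and cannot be told apart from methylation without EZH2; no biological explanation was tested.

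FLAG was found at 87.2% of the EZH2 peaks in the widest quartile group and at none in the narrowest. Chance meetings with wide peaks were argued against, because the highest of 1000 random placements gave 3.10% in the widest group. A FLAG list holding only the cores of peaks was first tested among EZH2 peaks of at least 3599 bp. Those above the median width exceeded the others by 48.8 points (85.9 against 37.1%, Fisher's exact p = 3.96e-40). By the rule set beforehand, this argued against the explanation. The bound was judged too low only after this value was seen, since the edge distances of 1400 to 2400 bp leave little room in many of those peaks. The distances come only from EZH2 peaks with FLAG, and 44 of 225 EZH2 peaks of 3399 to 5199 bp did carry FLAG. The first test was therefore left undecided. Among EZH2 peaks of at least 5999 bp, those above the median width exceeded the others by 5.15 points (158 of 180, 82.1 to 92.2%, against 157 of 190, 76.5 to 87.7%, Fisher's exact p = 0.189). A candidate explanation is that weaker FLAG enrichment was called only over the centres of sites, which cannot be told apart from a true absence of EZHIP at small EZH2 sites without signal values; no biological explanation was tested.

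No EZH2 peak lay past 144516199 on chromosome 7, although H3K27me3 and FLAG peaks did. A run of 14 H3K27me3 peaks without EZH2 arose anywhere in the genome in few of 1000 shuffles within chromosomes (permutation p = 0.00400), although chromosome 5 from 126086401 to 130863799 held a run of 15, so such peaks do gather. The 5 FLAG peaks there lack EZH2 by the definition of the stretch, and a run of 5 at any chromosome end was not met in 10000 shuffles of EZH2 status over FLAG peaks (permutation p = 0.0001, the smallest they can give), which bears on chance alone. Calls missing from the EZH2 list, for instance if EZH2 peaks were called with the chromosome lengths of another build, which could touch other chromosome ends too, and EZH2 below the calling threshold both stay open and untested.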
